A study of Rattus norvegicus with 54 samples.

How the data were processed

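Gene expression was measured with biotin-labelled total RNA on 1 Affymetrix gene-level array per sample, in 54 samples that the labels place in 18 groups of 3. The labels do not say whether replicates came from separate animals or cultures, so p-values measure only the spread between these samples, which may be technical. They do not say either whether cultures from different regions shared animals. The array type, genome build and annotation are not given in the sources used here, so no coordinates are printed.

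The authors deposited intensity values per probe set on a linear scale. Per the file headers, these are PLIER summaries after a GC-based background correction and a global median normalization. Affymetrix Expression Console is named in the submitters' processing notes, without a version. The same 54 columns of values stood in both deposited tables. The authors' deposited table also gives an unadjusted p-value, a ratio and a signed fold change for each of its comparisons, with no adjusted p. Its p-values matched an equal-variance test recomputed here on the linear signals, within 1e-06, for all probe sets listed. Each ratio was the ratio of the group means. No column of per-sample values belonged to an unknown sample.

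Each table held 29215 probe sets, of which 27342 were main probe sets and the others were controls. Of the main probe sets, 19863 had 1 gene symbol, 1396 had several and 6083 had none, and only the first kind was named. Symbols were updated through the gene identifier with the RefSeq gene table of assembly GRCr8, which held 18586 of these probe sets and changed the symbol of 5605. The table was used for names only.

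Signals were analysed as log2(signal + 16), so a fold change of a dim gene is understated. A probe set was tested when its signal was above 50 on at least 3 arrays of the fit, the signal limit being the one in the design text. Each comparison was fitted with limma 3.58.1 (lmFit and eBayes, two-sided) in R 4.3.3, with Benjamini-Hochberg adjustment over the probe sets tested. Every adjusted p for a gene is from that fit. A probe set was called at an adjusted p of 0.05 or less and a fold of at least 1.2, the limits in the design text. Each EAE comparison used only the 6 arrays of its region and stage. Effects averaged over regions, and differences between effects, were contrasts in 1 fit over the groups concerned. Errors beside log2 values are standard errors of the fit unless named as SD.

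Before the data were examined, 32 gene lists were fixed, with markers of other cell types that cultures or tissue could hold. Each was tested in each comparison with camera at a preset inter-gene correlation of 0.01, and again with an estimated one. Of 555 list tests, 190 were called with the preset correlation and 2 with the estimated one, both for microglia and macrophage genes, in the undifferentiated mean EAE effect and in its difference between cord and SVZ. List scores are means of log2(signal + 16) over the list's genes on an array.

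The rule for named genes was also fixed then. It took, per comparison, the 10 rising and the 10 falling called genes with the largest change whose groups did not overlap, or whose sign was the same in every region. Where fewer than 3 were called in a direction it took the 3 with the smallest p. It added up to 4 called members of each list and a fixed set of marker genes. The text uses a subset of these, picked after their values were seen, as the rule allows.

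Alternatives set before the data were seen were log2(signal + 1), no signal filter, quantile normalization, all 18 groups in 1 fit, a replicate block, the methods' t-test and leaving out replicates. A scaling to the 75th percentile, and a run without 5 arrays poorly correlated with their group, were added after seeing the data. The correlation limit for the latter, 0.96, was set after seeing the correlations. Besides the main one there were 66 settings over the 18 comparisons and the list tests, 57 of which leave out replicates. Each comparison was run only under the settings that apply to it. A replicate number was left out of all groups at once where a contrast spans several regions. No 2 arrays were identical, and the highest correlation between any pair was 0.995.

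Other groupings of the same arrays were counted for each comparison. All 10 splits were used for 3 arrays against 3, and 100 seeded label shuffles, the real one included, for the others. For cord against SVZ, the counting was changed after a first run to count each set of 3 arrays standing as SVZ once. It was then set back to the first form, because the change hid a high count. The fit was tested on simulated data with known changed genes. The simulated noise was independent between probe sets and equally wide in all groups of a comparison. Real arrays differ from that: the median SD was 0.271 in undifferentiated cervical naive and 0.158 in cervical EAE arrays, and scores of whole lists moved together. The counts that follow hold for the simulated setting only. For the undifferentiated caudal comparison the fit called 9 of 67 genes at 1.5-fold, 44 of 67 at 2-fold and 61 of 66 at 4-fold, and 7 unchanged ones. Recovery varied: for undifferentiated SVZ it was 52, 65 and 66, with 14 unchanged genes called, and for the undifferentiated cord minus SVZ effect 12, 35 and 62, with 15 unchanged genes called. In these runs the share of wrong calls passed 0.05 in more than 1 comparison, and was largest for the last. In the other 4 simulated comparisons between 2 and 10 unchanged genes were called. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.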

Results

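The data were 54 expression profiles of the central nervous system of Dark Agouti rats. Neural progenitor cell (NPC) cultures, which are grown from the multipotent precursors of the adult brain and spinal cord, came from 4 regions. These were the subventricular zone (SVZ), a germinal zone along the forebrain ventricles, and the cervical, thoracic and caudal spinal cord. The rats were naive or had experimental autoimmune encephalomyelitis (EAE), an induced inflammatory disease that serves as a model of multiple sclerosis. Cultures were profiled undifferentiated, after passage 2, or after 5 days of differentiation, and SVZ biopsies were profiled without culture. Each of the 18 groups held 3 arrays, and that number limits the precision. The median signal of the main probe sets lay between 51.6 and 120 on the 54 arrays, against 19 to 36.1 for background probe sets, and 50.5% to 74.5% of main probe sets exceeded a signal of 50.

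**Figure D1:**
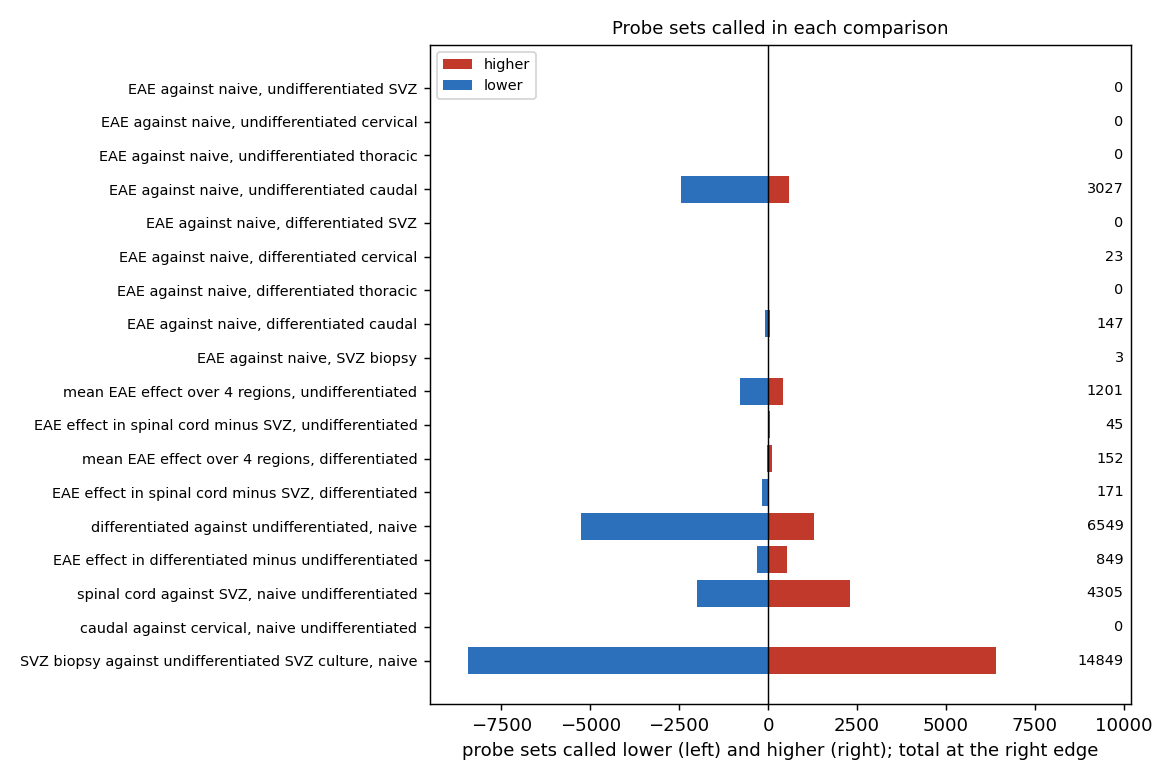
Number of probe sets called lower (bars to the left) and higher (bars to the right) in each of the 18 comparisons, with the total at the right edge. Counts ran from 0 to 14849, and among the EAE comparisons of single regions the undifferentiated caudal cultures had 3027.

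The first question was how cultures from cord and SVZ differed without disease. In naive undifferentiated cord cultures the transcription factor genes Lhx2 and Emx2 were lower by log2 differences of -3.76 ± 0.11 (adjusted p = 1.57e-08) and -4.39 ± 0.30. Of 16 forebrain regional factors 5 fell, with 5 falling and 1 rising adjusted over the list alone (adjusted p = 0.612 with an estimated correlation). Hox genes, which set position along the body axis, were higher, with Hoxa5 at 4.75 ± 0.43, Hoxa2 at 2.99 ± 0.24 and Hoxa7 at 2.40 ± 0.18. Myelin genes were also higher in cord cultures, among them Cldn11 at 5.09 ± 0.41 and Mbp, a structural myelin protein, at 3.80 ± 0.50. Of 26 Hox genes tested 15 rose, and 16 when adjusted over the list alone (adjusted p = 0.141 with an estimated correlation). Of 21 myelin genes 20 rose, also 20 adjusted over the list alone (adjusted p = 0.384 with an estimated correlation). Oligodendrocyte progenitor genes rose in 7 and fell in 1 of 16, with 9 and 1 adjusted over the list alone (adjusted p = 0.66 with an estimated correlation), including Sox10 at 3.66 ± 0.42. Of 17 neural stem and progenitor genes 10 fell, 12 adjusted over the list alone (adjusted p = 0.0767 with an estimated correlation), including Nes at -2.27 ± 0.25 and Egfr at -4.45 ± 0.87. Of 18 Notch pathway genes 8 fell, with 12 falling and 1 rising adjusted over the list alone (adjusted p = 0.0584 with an estimated correlation). Immediate early genes, which respond within minutes to stimulation, fell in 10 of 18, 13 adjusted over the list alone (adjusted p = 0.337 with an estimated correlation), with Arc at -4.71 ± 0.35. In all, 4305 of 18835 probe sets were called, 2302 higher and 2003 lower in cord. The count was 908 without replicate 1 of each group and 1853 without replicate 2. It was 6465 with all groups in 1 fit and 7694 without the arrays least like their group.

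Fibroblast genes were among several lists that differed between the naive cord cultures. Mgp, a matrix protein, stood 6.34 (SE 1.5) higher in cord than in SVZ, and of 19 pericyte and fibroblast genes 3 rose and 2 fell, with 6 and 2 adjusted over the list alone. The list score was 9.36 on undifferentiated cervical naive replicate 3 and 9.64 and 9.43 on thoracic naive replicates 1 and 3. It was 5.89 on thoracic naive replicate 2 and at most 6.08 on the 3 naive SVZ arrays. The same 3 cord arrays had reactive astrocyte scores of 9.61, 9.24 and 9.56 and cytokine scores of 8.87, 8.08 and 8.68, and 13.9%, 8.26% and 11.8% of their signal in the top 100 probe sets. Caudal and cervical naive cultures were compared to ask whether cord level mattered. No probe set of 17918 was called by limma, 1413 had an unadjusted p under 0.05, and the methods' t-test also called 0. The smallest p values belonged to Chdh, at 1.04 ± 0.13, and Ccl3, a chemokine, at -1.20 ± 0.15, with an adjusted p of 0.546 for both. With all groups in 1 fit the count was 386.

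Differentiation was compared with the undifferentiated state in naive cultures, averaged over the 4 regions. Of 18 immediate early genes 16 fell, 17 adjusted over the list alone (adjusted p = 0.0598 with an estimated correlation), with Fosb at -5.05 ± 0.33, Nr4a1 at -3.37 ± 0.15 and Fos at -3.31 ± 0.19 (adjusted p = 1.22e-09). Of 32 cell cycle genes 28 fell, 30 adjusted over the list alone (adjusted p = 0.957 with an estimated correlation), including Mki67, a proliferation marker, at -1.67 ± 0.42 and Cenpf at -1.82 ± 0.40. Of 18 Notch genes 12 fell, also 12 adjusted over the list alone (adjusted p = 0.489 with an estimated correlation), with Nrarp at -2.39 ± 0.23 and Hes1 at -2.52 ± 0.49. Of 17 stem and progenitor genes 12 fell, again 12 adjusted over the list alone (adjusted p = 0.575 with an estimated correlation). Of 21 myelin genes 11 rose, 12 adjusted over the list alone (adjusted p = 0.575 with an estimated correlation), with Mobp at 2.85 ± 0.48. Gfap and Aqp4, both astrocyte genes, rose by 1.42 ± 0.51 and 1.95 ± 0.62 on average, but the SVZ cultures carried this, at 6.16 for Gfap against 0.74, -0.85 and -0.36 in cervical, thoracic and caudal cultures. Pdgfra, a receptor of oligodendrocyte progenitors, fell on average by 0.81 but stood 1.77 higher in SVZ. The fit called 6549 of 19576 probe sets, 1300 higher and 5249 lower, and quantile normalization gave 3122 and 2837 and moved the median change of all probe sets from -0.15 to 0.02. Without replicate 1 of each group the count was 3254, and without replicate 2 it was 2858.

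SVZ biopsies were set against undifferentiated SVZ cultures to show what culture keeps of the tissue. Of 17 striatal and mature neuron genes 15 rose and 1 fell in biopsies, likewise adjusted over the list alone (adjusted p = 0.213 with an estimated correlation). The risers among neuronal genes included Drd2, a dopamine receptor of the striatum, at 7.45 ± 0.12 (adjusted p = 9.13e-14), Gad2 at 6.74 ± 0.11 and Snap25 at 6.43 ± 0.12. Microglia and macrophage genes rose in 20 and fell in 1 of 21, likewise adjusted over the list alone (adjusted p = 0.213 with an estimated correlation), with Ctss at 6.07 ± 0.15. All 11 endothelial genes tested rose, also adjusted over the list alone (adjusted p = 0.313 with an estimated correlation), with Flt1 at 4.01 ± 0.13. Of 20 myelin genes 17 rose and 2 fell, likewise adjusted over the list alone (adjusted p = 0.471 with an estimated correlation), with Mobp at 4.41 ± 0.23. Of 19 ependymal genes 17 rose, also 17 adjusted over the list alone (adjusted p = 0.283 with an estimated correlation). Astrocyte genes went both ways, with Gfap at 4.72 ± 0.12 and Slc1a3 at -1.06 ± 0.10, and of 17 in the list 8 rose and 6 fell, likewise adjusted over the list alone. Cell cycle genes fell in 30 of 32, also 30 adjusted over the list alone (adjusted p = 0.471 with an estimated correlation). Cholesterol synthesis genes fell in 21 and rose in 1 of 22, likewise adjusted over the list alone (adjusted p = 0.283 with an estimated correlation), with Idi1 at -3.40 ± 0.15. Cultures also had more Nes, an intermediate filament of progenitors, at -5.21 ± 0.10 for biopsy minus culture, Egfr at -3.35 ± 0.11 and Fos at -6.06 ± 0.11. In all, 14849 of 19305 probe sets were called, 6415 higher and 8434 lower in biopsies. Scaling to the 75th percentile, an added alternative, gave 8292 higher and 6838 lower.

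The main question was what EAE changes in NPC cultures. Averaged over the 4 regions, undifferentiated EAE cultures had more RNA of macrophage and microglia genes. The complement genes C1qc and C1qa stood 3.44 ± 0.23 and 3.43 ± 0.25 higher, the chemokine Ccl3 3.64 ± 0.23 higher (adjusted p = 3.61e-08), the lysosomal protease Ctss 2.88 ± 0.21 and the receptor Csf1r 2.77 ± 0.20. The cord cultures carried the change: C1qc was 4.41, 4.65 and 4.48 higher in cervical, thoracic and caudal cultures and 0.20 in SVZ. Of 22 microglia and macrophage genes 19 rose, 20 adjusted over the list alone, and the list was also called with an estimated correlation (adjusted p = 0.0101 with an estimated correlation). Of 14 antigen presentation genes 3 rose, also 3 adjusted over the list alone (adjusted p = 0.506 with an estimated correlation), including RT1-DMb at 1.81 ± 0.19. Of 18 Notch genes 3 fell, 5 adjusted over the list alone (adjusted p = 0.449 with an estimated correlation), among them Hey2 at -0.68 ± 0.13. Genes that fell included Cdk6, a cell cycle kinase, at -1.38 ± 0.25 and the matrix gene Aspn at -2.90 ± 0.81, with little change in SVZ, at -0.25 and -0.13. The mean fibroblast score was also higher in naive than in EAE cord cultures, at 7.59 against 6.61 in cervical, 8.32 against 7.58 in thoracic and 7.64 against 6.26 in caudal cultures. Only the caudal arrays stood apart, with naive ones from 7.37 and EAE ones up to 7.01. Thoracic naive replicate 2, at 5.89, lay below all EAE arrays of its region, the lowest at 7.29. Cervical naive replicate 2, at 6.08, lay below EAE replicates 1 and 3, at 6.78 and 7.24. Of 19 pericyte and fibroblast genes 1 fell, also 1 adjusted over the list alone (adjusted p = 0.591 with an estimated correlation). In all, 1201 of 19286 probe sets were called, 422 higher and 779 lower, against 912 and 521 after quantile normalization. Without replicate 1 of each group the count was 145 and without replicate 3 it was 125. It was 1849 with all groups in 1 fit and 3319 without the arrays least like their group.

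The difference itself was tested next, as the EAE effect in cord minus that in SVZ. C1qa differed by 4.93 ± 0.57, Ccl3 by 4.75 ± 0.52, C1qc by 4.31 ± 0.54, Mpeg1 by 3.67 ± 0.41 and Csf1r by 3.47 ± 0.45, with an adjusted p of 0.000207 for C1qa. Of 22 microglia and macrophage genes 13 rose, 18 adjusted over the list alone (adjusted p = 0.00139 with an estimated correlation). In all, 45 of 19286 probe sets were called, 43 higher and 2 lower, the latter Ccdc141 at -1.86 ± 0.34 and Slc6a9 at -0.98 ± 0.20. Quantile normalization moved the median change of all probe sets from -0.10 to 0.02 and called 48. The count was 4 without replicate 1 of each group and 18 without replicate 3. The direction of the calls was less fixed: without replicate 2 of each group 24 were higher and 40 lower, and without the arrays least like their group 185 were higher and 482 lower of 667.

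**Figure D2:**
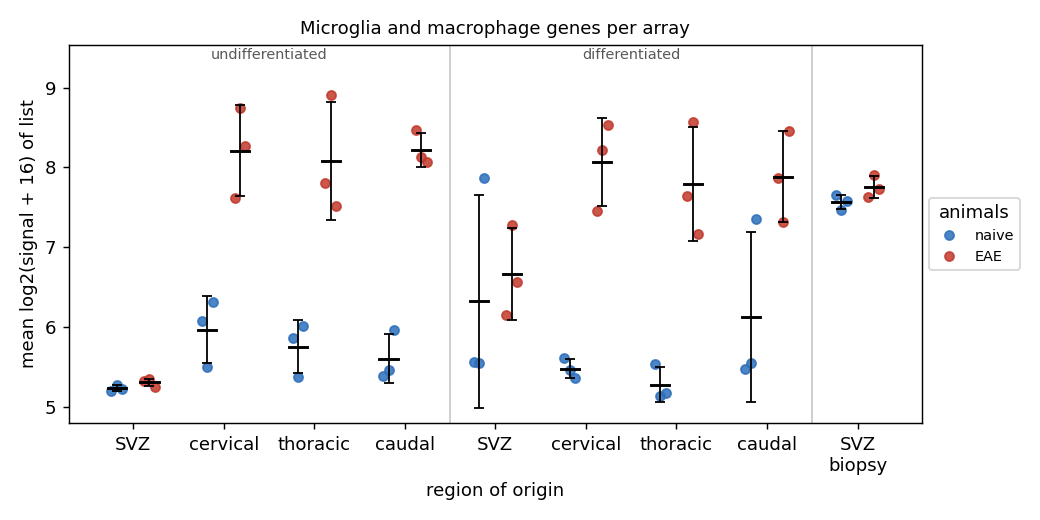
Mean log2(signal + 16) of the microglia and macrophage genes on each array (points; blue naive, red EAE), by region of origin and stage, with group mean (thick bar) and SD (whiskers, n = 3). Undifferentiated EAE cord arrays lay between 7.52 and 8.91 and naive ones between 5.38 and 6.31, while differentiated SVZ and caudal naive replicate 3 stood at 7.86 and 7.35.

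In undifferentiated SVZ cultures no probe set of 16535 was called by limma, 1976 had an unadjusted p under 0.05, and the methods' t-test called 0. Rnase4 stood 0.70 ± 0.08 higher in EAE (adjusted p = 0.0818), and Dusp6 and Spry4, both feedback inhibitors of growth factor signalling, 1.03 ± 0.16 and 0.80 ± 0.12 higher, none past the threshold. Astrocyte genes were called as a list with the preset correlation, with 0 of 14 called and 7 rising adjusted over the list alone (adjusted p = 0.186 with an estimated correlation). Without naive replicate 3 the count was 5, it was 1 without EAE replicate 1 and 1 without EAE replicate 3, and it was 3 with all groups in 1 fit.

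In undifferentiated cervical cultures C1qc stood 4.41 ± 0.53, Mpeg1 3.60 ± 0.35 and C1qb 3.04 ± 0.35 higher in EAE, with an adjusted p of 0.256 each. limma called 0 of 17302 probe sets, 1865 had an unadjusted p under 0.05, and the methods' t-test called 0. Of 21 microglia and macrophage genes 0 were called, and 15 rose adjusted over the list alone (adjusted p = 0.409 with an estimated correlation). Without naive replicate 3, the array with the fibroblast score of 9.36, the count was 37, it was 1 without EAE replicate 1, and it was 988 with all groups in 1 fit.

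In undifferentiated thoracic cultures Ccl3 stood 4.77 ± 0.42, the lysozyme gene Lyz2 3.63 ± 0.30 and Fcrl2 3.43 ± 0.26 higher in EAE, with an adjusted p of 0.0793 each. limma called 0 of 17676 probe sets, 1115 had an unadjusted p under 0.05, and the methods' t-test called 0. Of 22 microglia and macrophage genes 0 were called, and 18 rose adjusted over the list alone (adjusted p = 0.746 with an estimated correlation). Without naive replicate 2, whose fibroblast score was 5.89 against 9.64 and 9.43 on the others, the count was 2085. It was 199 with all groups in 1 fit and 3 with log2(signal + 1).

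With all groups in 1 fit, differentiated thoracic cultures had 1896 calls against 1680 in undifferentiated caudal cultures. That fit pools the spread, which understates the error of differentiated thoracic naive arrays, the widest group with a median SD of 0.3775. With each region fitted alone, undifferentiated caudal cultures showed the most calls among the single regions. Of 21 microglia and macrophage genes 20 rose, also 20 adjusted over the list alone (adjusted p = 0.419 with an estimated correlation), with Ccl3 at 5.56 ± 0.21 (adjusted p = 6.34e-07), C1qa at 4.82 ± 0.29, Ctss at 4.41 ± 0.23 and Csf1r at 3.91 ± 0.20. Of 23 hypoxia and glycolysis genes 12 rose and 2 fell, with 14 and 2 adjusted over the list alone (adjusted p = 0.558 with an estimated correlation), the risers including Vegfa at 2.94 ± 0.23, Pdk1 at 2.49 ± 0.26 and Tpi1 at 1.62 ± 0.18. Of 21 myelin genes 17 fell, 19 adjusted over the list alone (adjusted p = 0.558 with an estimated correlation), including Ermn at -2.54 ± 0.21, Opalin at -2.34 ± 0.24 and Mbp at -0.80 ± 0.15. Of 18 pericyte and fibroblast genes 13 fell, also 13 adjusted over the list alone (adjusted p = 0.583 with an estimated correlation), including Col3a1 at -3.70 ± 0.79, and the matrix gene Aspn stood at -3.86 ± 0.23. Of 16 astrocyte genes 8 fell and 2 rose, with 9 and 2 adjusted over the list alone, among them Mlc1 at -3.54 ± 0.54 and S100b at -2.28 ± 0.22, while Slc1a3 was not called, at 0.36 ± 0.23. Of 19 reactive astrocyte genes 9 fell and 1 rose, with 13 and 2 adjusted over the list alone (adjusted p = 0.583 with an estimated correlation).

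In undifferentiated caudal cultures 3027 of 17590 probe sets were called, 584 higher and 2443 lower, against 1707 and 1707 after quantile normalization, which moved the median change of all probe sets from -0.14 to 0.02. The authors' deposited table, after adjustment of its p-values here, had 202 calls, 33 higher and 169 lower, and 0 in each other EAE comparison. Without EAE replicate 1 the count was 1522, without EAE replicate 3 it was 1447, without naive replicate 1 it was 1790 and without naive replicate 3 it was 1849. It was 424 with the methods' t-test, run on log2 values and not on the linear signals behind the 202. With all groups in 1 fit it was 1680.

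Among differentiated cultures, averaged over the 4 regions, macrophage genes were again higher in EAE. Fcrl2 stood 3.22 ± 0.35 (adjusted p = 0.000361), Ctss 3.04 ± 0.46, C1qa 2.69 ± 0.42 and Adgre1, the F4/80 gene, 2.54 ± 0.29 higher. Of 22 microglia and macrophage genes 18 rose, 20 adjusted over the list alone (adjusted p = 0.083 with an estimated correlation). Genes that fell included Id1 and Id2, targets of BMP signalling, at -0.79 ± 0.18 and -0.75 ± 0.14. Of 28 BMP and TGF-beta pathway genes 2 fell, 3 adjusted over the list alone (adjusted p = 0.596 with an estimated correlation). In all, 152 of 19520 probe sets were called, 118 higher and 34 lower, against 234 and 115 after quantile normalization. The count was 7 without replicate 1 of each group, 0 without replicate 2, 221 without replicate 3 (94 higher, 127 lower), and 310 without the arrays least like their group. It was 422 with all groups in 1 fit, and 497 (453 higher, 44 lower) after scaling to the 75th percentile.

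The EAE effect in differentiated cord minus that in differentiated SVZ was tested in the same way. Of 34 interferon response genes 5 fell, 28 adjusted over the list alone (adjusted p = 0.667 with an estimated correlation). Ifit3 differed by -3.83 ± 0.51 (adjusted p = 0.00201), Cxcl10 by -3.03 ± 0.65, Oasl by -2.10 ± 0.49 and Ifit2 by -2.05 ± 0.46. The SVZ side includes naive replicate 3, whose interferon score of 7.08 stood apart from 8.63 and 8.57. Bmp4 differed by -3.23 ± 0.46, Entpd2 by -2.43 ± 0.24 and Hydin, a gene of motile cilia, by -3.49 ± 0.65. The score of the ependymal and cilia list was 6.31 on differentiated SVZ naive replicate 3 against 8.72 and 8.91 on the other naive arrays, and of its 19 genes 0 were called and 7 fell adjusted over the list alone (adjusted p = 0.667 with an estimated correlation). Of 22 microglia and macrophage genes 0 were called, and 19 rose adjusted over the list alone (adjusted p = 0.428 with an estimated correlation). The score of this list was 7.86 on SVZ naive replicate 3 against 5.56 and 5.54 on the other naive arrays, which lowers the SVZ effect. On caudal naive replicate 3 it was 7.35 against 5.47 and 5.54, which lowers the cord effect. In all, 171 of 19520 probe sets were called, 3 higher and 168 lower, against 21 and 27 after quantile normalization, which moved the median change of all probe sets from -0.19 to 0.05, and 87 and 18 after scaling to the 75th percentile. The count was 7 without replicate 1 of each group, 3 without replicate 2 and 44 without replicate 3. It was 67 with log2(signal + 1), 505 with all groups in 1 fit and 788 without the arrays least like their group.

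**Figure D3:**
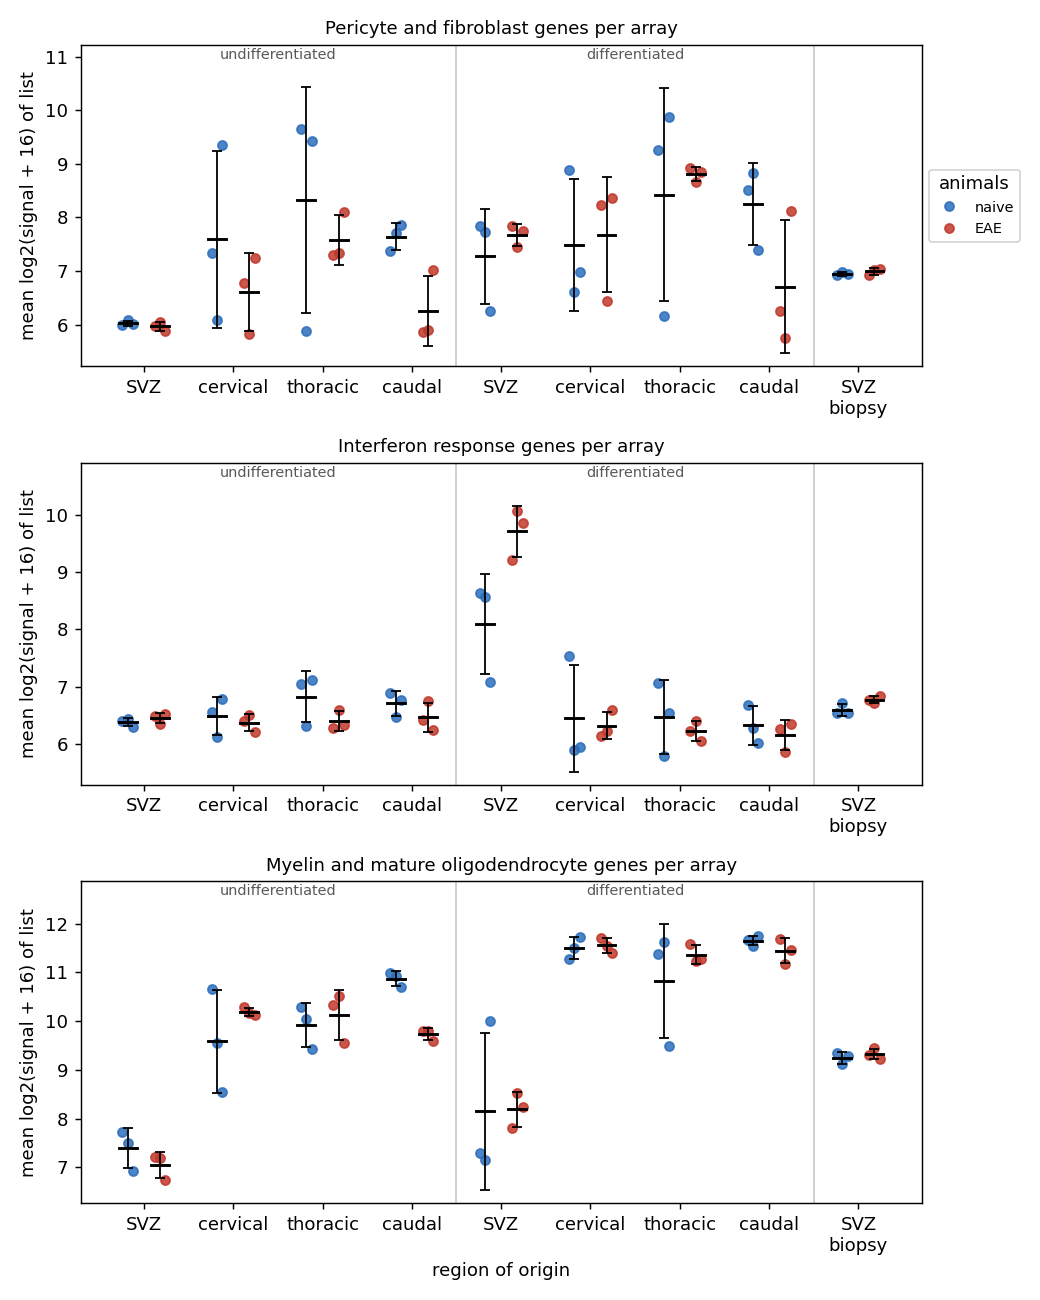
Mean log2(signal + 16) per array (points; blue naive, red EAE) of the fibroblast, interferon and myelin lists, by region of origin and stage, with group mean (thick bar) and SD (whiskers, n = 3). Interferon scores of differentiated SVZ arrays were 9.21 to 10.06 in EAE and 8.63, 8.57 and 7.08 in naive cultures.

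In differentiated SVZ cultures Uba7, an interferon-induced enzyme, stood 2.28 ± 0.24 and Neu4 1.40 ± 0.15 higher in EAE, with an adjusted p of 0.188 for both. limma called 0 of 17539 probe sets, 3242 had an unadjusted p under 0.05, and the methods' t-test called 0. Of 33 interferon response genes 0 were called, and 29 rose adjusted over the list alone (adjusted p = 0.782 with an estimated correlation). Naive replicate 3 stood apart, with a microglia score of 7.86 against 5.56 and 5.54, and a myelin score of 10 against 7.28 and 7.15. Without it the count was 1177, of which 1156 were higher, and it was 280 with all groups in 1 fit. Quantile normalization moved the median change of all probe sets from 0.14 to -0.03.

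In differentiated cervical cultures 23 of 17345 probe sets were called, 22 higher and 1, without a symbol, lower in EAE. Ctss rose by 4.45 ± 0.29 (adjusted p = 0.00385), C1qc by 3.99 ± 0.24, Csf1r by 3.44 ± 0.34 and Igf1, a growth factor, by 3.25 ± 0.31. Of 21 microglia and macrophage genes 10 rose, 19 adjusted over the list alone (adjusted p = 0.206 with an estimated correlation). The fibroblast score divided these 6 arrays, at 8.24, 8.36 and 8.89 on EAE replicates 1 and 3 and naive replicate 1 and 6.44, 6.60 and 6.98 on the others. The count was 3 without EAE replicate 1, 0 without EAE replicate 2, 0 without EAE replicate 3, 50 without naive replicate 1, 4 without naive replicate 2 and 0 without naive replicate 3. It was 0 with the methods' t-test and 58 with all groups in 1 fit.

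In differentiated thoracic cultures Lyz2 stood 4.47 ± 0.51, Ctss 3.99 ± 0.46 and Fcrl2 3.73 ± 0.36 higher in EAE, with an adjusted p of 0.13 each. limma called 0 of 17084 probe sets, 1044 had an unadjusted p under 0.05, and the methods' t-test called 0. Of 21 microglia and macrophage genes 0 were called, and 17 rose adjusted over the list alone (adjusted p = 0.746 with an estimated correlation). Of 30 cell cycle genes 0 were called, and 18 fell adjusted over the list alone (adjusted p = 0.746 with an estimated correlation). Without naive replicate 2, whose fibroblast score was 6.15 against 9.25 and 9.87, the count was 207, and without naive replicate 3 it was 15. With all groups in 1 fit it was 1896, but the naive arrays here had the widest spread of any group (median SD 0.3775), which pooling understates.

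In differentiated caudal cultures Fcrl2 rose by 3.97 ± 0.50 (adjusted p = 0.000505), Adgre1 by 3.55 ± 0.39 and Csf1r by 2.72 ± 0.52 in EAE. Cell cycle genes Ccna2 and Ccnb1 fell, at -1.21 ± 0.27 and -1.20 ± 0.28, as did Pdgfra at -1.36 ± 0.28 and Tgfb2 at -1.88 ± 0.32. Of 22 microglia and macrophage genes 13 rose, with 20 rising and 1 falling adjusted over the list alone (adjusted p = 0.399 with an estimated correlation). Of 29 cell cycle genes 4 fell, 21 adjusted over the list alone (adjusted p = 0.448 with an estimated correlation). Of 17 pericyte and fibroblast genes 2 fell, 14 adjusted over the list alone (adjusted p = 0.448 with an estimated correlation), and the list score was 8.52, 8.83 and 7.39 on naive and 6.26, 5.76 and 8.12 on EAE arrays. In all, 147 of 16522 probe sets were called, 55 higher and 92 lower, but 0 after quantile normalization, which moved the median change of all probe sets from -0.13 to 0.04, and 0 after scaling to the 75th percentile. EAE replicate 2 was the dimmest of these arrays, with a median signal of 53.7 against 70.1 and 78.2 on EAE replicates 1 and 3. On naive replicates 1, 2 and 3 it was 63.9, 84.2 and 70.6. The count was 0 without EAE replicate 2, 459 without EAE replicate 1, 719 without EAE replicate 3, and 286, 360 and 684 without naive replicates 1, 2 and 3. It was 8 with log2(signal + 1), 9 with no signal filter, 0 with the methods' t-test and 27 with all groups in 1 fit.

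The stage dependence of the EAE effect was tested as the effect in differentiated minus that in undifferentiated cultures. Ccl3 differed by -2.11 ± 0.33 (adjusted p = 0.000709) and Il1b, a cytokine, by -0.88 ± 0.19. The differentiated side includes naive replicate 3 of SVZ and of caudal cultures, with microglia scores of 7.86 and 7.35, above the other arrays of their groups. The glycolysis genes Tpi1 and Ldha differed by -0.91 ± 0.22 and -0.97 ± 0.23. Pcp4 differed by 2.26 ± 0.35, and Ifit3 by 1.22 ± 0.30, with 4.94 in SVZ and 0.02, 0.10 and -0.16 in cervical, thoracic and caudal cultures. Of 24 hypoxia and glycolysis genes 3 fell, with 4 falling and 1 rising adjusted over the list alone (adjusted p = 0.567 with an estimated correlation). Of 34 interferon response genes 2 rose, 3 adjusted over the list alone (adjusted p = 0.655 with an estimated correlation). In all, 849 of 20237 probe sets were called, 542 higher and 307 lower, against 737 and 751 after quantile normalization and 2307 and 568 after scaling to the 75th percentile. The count was 33, 161 and 14 without replicates 1, 2 and 3 of each group. It was 3492 without the arrays least like their group, where 1659 were higher and 1833 lower.

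In SVZ biopsies, taken to show the tissue itself, 3 of 19837 probe sets were called, all higher in EAE. These were Cd74 and RT1-Da, which serve antigen presentation by MHC class II, at 2.40 ± 0.26 (adjusted p = 9.95e-05) and 2.40 ± 0.24, and LOC686547 at 1.70 ± 0.14. The log2 value of Cd74 ran from 8.35 to 10.08 on EAE biopsies (SD 0.895) and from 6.61 to 6.79 on naive ones (SD 0.0976). Its standard error and adjusted p borrow from the spread of other probe sets. Of 15 antigen presentation genes 2 rose, 3 adjusted over the list alone (adjusted p = 0.0787 with an estimated correlation). Of 28 interferon response genes 0 were called, and 8 rose adjusted over the list alone (adjusted p = 0.943 with an estimated correlation). The count was 1 without EAE replicate 1, 100 without EAE replicate 2 (74 higher, 26 lower) and 10 without EAE replicate 3. It was 14 without naive replicate 1 and 161 without naive replicate 2 (133 higher, 28 lower). With a replicate block the count was 59, 33 higher and 26 lower, so the calls were not all higher in EAE under these settings. It was 0 after quantile normalization and with the methods' t-test, 1 after scaling to the 75th percentile and with all groups in 1 fit, and 5 with no signal filter.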

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

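In this part, the tests of an EAE culture under a naive label and of larger spread in the other cord regions were chosen before their results were seen. The other tests of explanations and the counts of other groupings were chosen only after.

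A test of the difference itself singled out 3 counts and the genes behind them. The EAE effect differed between cord and SVZ for 45 probe sets in undifferentiated cultures. Among named genes the log2 difference was 4.93 for C1qa, 4.75 for Ccl3, 4.31 for C1qc, 3.67 for Mpeg1, 3.47 for Csf1r, 3.38 for Ctss, 3.06 for Anxa3 and 2.81 for Aif1. It was -1.86 for Ccdc141 and -0.98 for Slc6a9. Without replicate 1 of each group the count was 4, and without replicate 3 it was 18.

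In differentiated cultures the EAE effect differed between cord and SVZ for 171 probe sets, or 3 without replicate 2 of each group, 7 without replicate 1 and 44 without replicate 3. The SVZ side includes naive replicate 3, whose microglia and macrophage score of 7.86 stood apart from 5.56 and 5.54. The difference was 3.30 for Clec7a and 2.64 for Cd4. It was -3.83 for Ifit3, -3.49 for Hydin, -3.23 for Bmp4, -3.03 for Cxcl10, -2.43 for Entpd2, -2.19 for Uba7, -2.10 for Oasl, -2.05 for Ifit2, -1.81 for Id4 and -1.14 for Fgfr3.

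Between differentiated and undifferentiated cultures the EAE effect differed for 849 probe sets, or 33, 161 and 14 without replicates 1, 2 and 3 of each group. The difference was 2.26 for Pcp4, 2.17 for Fxyd2, 1.55 for Slc39a12, 1.30 for Megf10 and 1.22 for Ifit3. It was -2.11 for Ccl3, -1.49 for Ltbp4, -1.44 for Ndrg2, -1.35 for Atp1b2, -1.30 for Id2, -1.27 for Emp2, -0.97 for Ldha, -0.91 for Tpi1, -0.88 for Il1b and -0.87 for Fgfr3.

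The first pattern weighed was the higher level of macrophage and microglia genes in EAE cord cultures. Array scaling was argued against, since the list's median log2 change in the undifferentiated mean EAE effect was 2.11 after quantile normalization (quartiles 1.16 and 2.61). Lymphocyte or erythrocyte RNA as a source was argued against, since 1 such gene was called higher, Cd4, which rat macrophages also express. Whether blood was carried into the cultures stays open. The cultures were profiled after passage 2, when such cells may be gone, and the test cannot see blood monocytes, which share macrophage genes. Macrophages or microglia in the cultures stay a candidate source: of 27 tested genes of a second macrophage list 17, or 63%, were called higher, between the bounds of 75% and 25%, with Mpeg1 at 2.66 and Lgals3 at 0.19. The disease itself, as a biological difference, stays open and was not tested apart from this.

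The second pattern was the macrophage signal in replicate 3 of the differentiated caudal and SVZ naive cultures, with scores of 7.35 and 7.86, and a swap of the caudal array with an EAE array of its region was argued against, since the lowest EAE score lay 1.78 above the other naive arrays. Whether the caudal array is an EAE culture under a naive label cannot be told: over 649 genes its median place between naive (0) and EAE (1) was 0.748 (quartiles 0.546 and 0.934), just short of the bound of 0.75 set beforehand. The genes were picked for a difference between the other naive arrays and EAE, which can place any left-out naive array nearer EAE. Signals were not rescaled, and of the 684 calls without this array 594 were lower in EAE. Its 75th percentile signal of 257.1 lay below 265.5 and 298.3 on the other naive arrays and within 190 to 276.6 on EAE arrays. Dimness could therefore also place it nearer EAE. For cord RNA mixed into the SVZ array, the test as first written gave 0.524 as the ratio of the median share at 15 Hox genes to that at 20 myelin genes, which meets its bound of 0.5, while over the 5 Hox genes at least 2-fold higher in cord, chosen after that, it was 0.0147. Of these 5, mixing at the myelin share with the lowest cord array would give signals of 34.1 for Hoxa2, 85.1 for Hoxa4, 34.5 for Hoxa5, 38.7 for Hoxa7 and 53.8 for Hoxc4, and the array had 17.3, 62.2, 4.64, 27 and 59.3, so 4 lay below and speak against mixing, at low signals. A last test set the median share of SVZ signal lost, 0.497 (quartiles 0.0631 and 0.745), against that of cord signal gained, 0.284 (0.198 and 0.373), and the difference of 0.213 lay between its bounds of 0.1 and 0.25, so the tests do not settle mixing and it stays open.

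The third pattern was the 3027 calls in undifferentiated caudal cultures beside 0 in the other 3 regions. Array scaling was argued against as the whole cause, since 75.6% of the calls were made again after quantile normalization. Larger spread between arrays was present in the naive cultures of the other cord regions. The median SD was 0.271 in cervical and 0.258 in thoracic against 0.163 in caudal naive arrays. In EAE arrays it was 0.158, 0.196 and 0.167 in that order. With the spread pooled over all groups the counts were 988 in cervical, 199 in thoracic and 1680 in caudal cultures. How much of the difference in counts the spread accounts for stays open. The test set for it compared directions, not spread. Of the called probe sets 51% went the same way in both cervical and thoracic cultures, between the bounds of 60% and 35%. The shares were 58.5% in cervical, 71.6% in thoracic and 42.3% in SVZ cultures taken singly. Whether the disease acts differently on caudal cord was not tested.

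Groupings of the same arrays other than the real one were counted for each result. In 1 of 100 groupings, the real one, the count was reached for the undifferentiated mean EAE effect (1201, highest other 133) and its difference between cord and SVZ (45 and 2). The same held for the differentiated mean (152 and 0), its difference between cord and SVZ (171 and 60), naive differentiation (6549 and 521) and the difference between stages (849 and 6). So no other shuffle drawn reached the count for these 6, which speaks against a chance labelling of these arrays only. Disease labels were shuffled within each region and stage, or stage labels within each region for naive differentiation. Shuffling disease labels removes the EAE effect everywhere, so it cannot test whether that effect differs between cord and SVZ or between stages. The shuffles cannot exclude chance between animals either, since replicates may not be separate animals and regions may share them. For naive cord against SVZ the real grouping was also the 1 of 100 with 4305, the highest other being 3950, in which the 3 SVZ arrays stayed together and only the cord labels moved. Outside that draw, every set of 3 of the 12 arrays, 220 in all, was tried once in place of SVZ, and 1 set without any SVZ array passed the real count. It held cervical naive replicate 3 and thoracic naive replicates 1 and 3, and called 8614 with the other labels in their given order. These 3 had fibroblast scores of at least 9.36 against at most 7.85 on the others, which points to a structure among the cord arrays. The counts do not rank it against the difference between cord and SVZ, since the set was picked from 220 and differences within the cord groups widen the spread behind the 4305, and the count without the arrays least like their group was 7694.

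For 3 arrays against 3 the 10 splits are too few for a share under 0.05. The real count and the highest other were 0 and 2 in undifferentiated SVZ, 0 and 0 in cervical, 0 and 0 in thoracic and 3027 and 0 in caudal cultures. They were 0 and 0 in differentiated SVZ, 23 and 51 in cervical, 0 and 0 in thoracic and 147 and 195 in caudal cultures. They were 3 and 258 in biopsies, 0 and 0 for caudal against cervical and 14849 and 0 for biopsy against culture. As many calls as the real split came from 2 of 10 splits in differentiated cervical and caudal cultures and 4 of 10 in biopsies, and from 10 of 10 where the real count was 0. In differentiated cervical cultures the split with 51 set EAE replicates 1 and 3 with naive replicate 1 against the others, with fibroblast scores of 8.24, 8.36 and 8.89 against 6.44, 6.60 and 6.98. In differentiated caudal cultures the split with 195 set EAE replicates 1 and 2 with naive replicate 3, the array in doubt, against the others, and these had the lower fibroblast scores, 6.26, 5.76 and 7.39 against 8.12, 8.52 and 8.83. In biopsies the split with 258 set EAE replicates 1 and 3 with naive replicate 2 against the others, and no feature of that split was tested. The cervical and caudal splits follow the fibroblast score. Whether a structure apart from the disease lies behind any of these splits was not tested.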

How the results depend on the processing

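The scaling to the 75th percentile and the run without the 5 arrays least like their group were chosen after seeing the data. The other alternatives were planned. The 223 pairs of a called gene and a comparison gave 2379 values under the alternatives. Of these, 1949 kept direction and side of the threshold, 430 kept direction but no longer passed, and 0 reversed. The lack of reversals says little. Fitting all groups together or dropping the signal filter leaves the log2 difference itself unchanged, so neither can reverse it. Many of the genes were also picked for a large change without overlap of the groups, or for the same sign in every region. The cause of the changes below was not tested, except that leaving out arrays leaves fewer samples. The arrays' signal over background, with medians of 51.6 to 120 against 19 to 36.1, limits what can be said of dim genes.

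The fit of all 18 groups pools the spread, so it understates the error of groups with a wide one. Among these were differentiated thoracic naive arrays (median SD 0.3775) and undifferentiated cervical naive arrays (0.2714). With all 18 groups in 1 fit, undifferentiated EAE counts became 3 in SVZ, 988 in cervical, 199 in thoracic and 1680 in caudal cultures. Differentiated ones became 280, 58, 1896 and 27 in that order of regions, and the biopsy count 1. The undifferentiated and differentiated mean EAE effects became 1849 and 422, the differentiated cord minus SVZ effect 505, naive cord against SVZ 6465 and caudal against cervical 386. With the methods' t-test the count was 424 in undifferentiated caudal cultures and 0 in differentiated cervical, differentiated caudal and biopsy samples. With log2(signal + 1) it was 3 in undifferentiated thoracic, 8 in differentiated caudal cultures and 67 for the differentiated cord minus SVZ effect. With no signal filter it was 9 in differentiated caudal cultures and 5 in biopsies.

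After quantile normalization the count was 0 in differentiated caudal cultures and in biopsies, 349 for the differentiated mean EAE effect, 48 for its cord minus SVZ difference and 1488 for the stage difference. With the 75th percentile scaling these were 0, 1, 497, 105 and 2875. Without the arrays least like their group the count was 3319 and 310 for the undifferentiated and differentiated mean EAE effects, 667 and 788 for their cord minus SVZ differences, 3492 for the stage difference and 7694 for naive cord against SVZ. With an estimated correlation 2 list tests were called instead of 190.

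With a replicate block the count was 15 in differentiated thoracic cultures, 395 in differentiated caudal cultures, 59 in biopsies, 492 for the undifferentiated mean EAE effect and 339 for the differentiated cord minus SVZ effect. In undifferentiated caudal cultures it was 2122. Whether the numbers pair the samples is not settled. In no comparison was every correlation between same-numbered samples over 0.1. Every sample matched its own number best only for caudal against cervical, as 3 of 3 pairs. Over the groups of the stage difference, 117 of 360 correlations were over 0.1, the highest 0.921, and 150 matched their own number best. Some groups may thus share cultures or runs by number. A pairing of the stages by number within a region was not fitted.

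Leaving out 1 replicate gave 0 to 5 calls in undifferentiated SVZ, 0 to 37 in cervical, 0 to 2085 in thoracic (2085 without naive replicate 2) and 1447 to 3554 in caudal cultures. It gave 0 to 1177 in differentiated SVZ (1177 without naive replicate 3), 0 to 50 in cervical, 0 to 207 in thoracic, 0 to 719 in caudal cultures and 1 to 161 in biopsies. For the undifferentiated mean EAE effect the range was 125 to 1676 and for its cord minus SVZ difference 4 to 64. For the differentiated ones it was 0 to 221 and 3 to 44, and for the stage difference 14 to 161. It was 2858 to 6595 for naive differentiation, 908 to 2951 for cord against SVZ, 0 to 0 for caudal against cervical and 11922 to 14398 for biopsy against culture.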

Other observations

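The values in this part were picked after the results were seen, and no explanation was tested for them. Interferon response genes were higher in the differentiated SVZ cultures than in other cultures by group mean, with and without EAE. The list score was 9.71 ± 0.45 (SD, n = 3) in EAE and 8.09 ± 0.88 in naive differentiated SVZ cultures, against 6.45 ± 0.09 and 6.38 ± 0.07 in the undifferentiated ones. In differentiated cord cultures the group means lay between 6.15 and 6.47. Single arrays overlapped, with 7.08 on differentiated SVZ naive replicate 3 and 7.52 on differentiated cervical naive replicate 1.

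In undifferentiated cervical and thoracic naive cultures the cell cycle score was lower on arrays with a high fibroblast score. The cell cycle score was 6.51 on undifferentiated cervical naive replicate 3, where the fibroblast score was 9.36, and 9.51 and 9.68 on replicates 1 and 2, where it was 7.33 and 6.08. On thoracic naive replicate 2 the cell cycle score was 9.96 and the fibroblast score 5.89, while replicates 1 and 3 had cell cycle scores of 8.18 and 7.48. Differentiated thoracic naive cultures went the other way, with cell cycle scores of 7.89, 7.05 and 7.69 beside fibroblast scores of 9.25, 6.15 and 9.87. So did differentiated cervical naive replicate 1, with 7.61 and 8.89 against 6.88 and 6.60 on replicate 2.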
